A study of Mus musculus with 27 samples.

How the data were processed

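RNA of B220-purified B cells was sequenced in 27 samples: 8 of non-malignant splenic B cells, 4 of them treated with LPS for 2 days, and 19 of lymphomas from lung or lymph nodes. Total RNA was depleted of ribosomal RNA and made into stranded libraries that were read from both ends, per the labels' protocols. Per the submitters' processing notes, the tools were FastQC and kallisto 0.43, which assigns reads to transcripts without aligning them base by base, and the build was mm10 (GRCm38). The transcript annotation and the strand setting of the counting are not given in the sources used here, so overlapping and antisense genes may share reads. The authors' deposited table held TPM (a relative abundance per transcript) for 88198 Ensembl transcripts, with their coordinates. Transcript TPM were summed to 30735 genes, and gene symbols were matched by Ensembl identifier; 740 genes had none and were kept under their identifiers. Kallisto divides reads that fit several transcripts between them, so values of near-identical genes, such as immunoglobulin variable genes, globins, histones and ribosomal protein pseudogenes, are uncertain.

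TPM keeps no depth by itself. The deposited table also gave 1 effective length per transcript, and TPM times this length was divided by its most frequent low value, taken as 1 read pair. Of values between 1 and 20 read pairs in genes with 1 transcript, 60.7 to 75.8% came out whole within 0.02 reads. The depth was about 11530400 to 32029600 read pairs, with a median of 21463300. Since this share is well short of complete, recovered reads served only for the depth and for 1 alternative (voom). A floor of 3 read pairs limits what low values can show, and it covers counting error only. No depth was used to weight samples.

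Groups were taken from the labels. Sample names of the lymphomas were written in 2 styles, with their parts joined (all from lung) or separated, and this style was treated as a possible batch. The labels name hv, cr and co without saying what the names stand for. 1 lung lymphoma is titled hv and described as CO; it was used among all lymphomas and left out of comparisons between lines and sites. The comparisons, tests, gene lists and named-gene rule, and the alternatives unless stated otherwise, were chosen before the data were examined. Genes with TPM of 1 or more in at least 4 samples of a fit were tested on log2(TPM + 1) with limma 3.58.1 (trend and robust settings) in R 4.3.3 with the data.table package (1.17.8), and p-values were adjusted by the Benjamini-Hochberg method with a threshold of 0.05. Fold changes are on the log2(TPM + 1) scale, which understates changes of low genes. LPS against resting, lymphoma against resting and lymphoma against LPS were fitted each on their own groups. Lines and sites were fitted together on 18 lymphomas, with site and line as terms.

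23 biology lists and 13 marker lists of other cell types were fixed from general knowledge. They covered MYC targets, ribosome biogenesis, S phase, G2/M, nucleotide and one-carbon metabolism, glycolysis, oxidative phosphorylation, unfolded protein response, cholesterol synthesis, follicular and naive B cells, marginal zone and B1 cells, germinal centre B cells, plasma cells, early B-cell development, B-cell receptor signalling, MHC class II, NF-kappaB, interferon response, p53 targets, the BCL2 family, histones, immediate early genes and ribosomal proteins. The marker lists covered B cells, T cells, NK cells, macrophages, alveolar macrophages, neutrophils, dendritic cells, lung epithelium, erythroid cells, platelets, pancreas with adipose tissue, and fibroblasts. The endothelium list had 2 measured members, where a test needed 3. Lists were tested by camera with a preset correlation of 0.01, with an estimated correlation, and by fry. The named genes were the 10 highest and the 10 lowest log2 fold changes among called genes with a mean TPM of 5 or more in the higher group and no overlap between groups, without variable segments, predicted genes and pseudogenes. Further named genes were up to 8 each way for lines and sites, or the 3 smallest p-values where none passed, 51 fixed genes, and the 4 members of each list with the largest changes, taken from the called ones where there were any. Wrap53, Fxr2, Mtap, Klhl9 and the Gm genes were named after their values were seen. 2 genes that met these rules are not reported here.

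Shares of immunoglobulin constant regions and of the top variable gene, and Myc, were compared by exact two-sided permutation tests of the mean (Benjamini-Hochberg over 54, 12 and 6 tests). Correlations of Myc with lists used Pearson's r and Spearman's rho with permutation p-values from 100000 resamples, adjusted over 5. The lambda share used Iglc2 against Igkc. Python 3.11.15, pandas 2.3.3, numpy 2.4.6, scipy 1.17.1 and matplotlib 3.10.9 were used. The tests were tried on simulated data. Changes were planted only in genes above a limit on the mean, drawn independently and with the same spread in both groups. Recovery of lower, correlated or unevenly spread genes was not covered. False calls made up 4.03% (lymphoma against resting) to 7.24% (hv against cr) of the simulated calls. For LPS against resting, limma recovered 53.8% of genes simulated with a log2 change of 1 and 93.5% of those with 2. For lymphoma against resting, limma recovered 52.4% of genes simulated with a log2 change of 1 and 91.8% of those with 2. For lymphoma against LPS, limma recovered 44.1% of genes simulated with a log2 change of 1 and 87.8% of those with 2. For hv against cr, limma recovered 41.6% of genes simulated with a log2 change of 1 and 93.7% of those with 2. For hv against co, limma recovered 34.7% of genes simulated with a log2 change of 1 and 88.6% of those with 2. For cr against co, limma recovered 36.2% of genes simulated with a log2 change of 1 and 82.1% of those with 2. For lymph node against lung, limma recovered 48.96% of genes simulated with a log2 change of 1 and 91.3% of those with 2. The alternatives were other pseudocounts (0.1 and 5), other filters on low values, median-of-ratios scaling, rescaling without immunoglobulin and mitochondrial genes, a variance per group, no trend, single transcripts, subsets of samples, and leaving out single samples. Against lymphomas only the non-malignant samples were left out in turn, for pairs of lines those of the compared lines, and for sites only the node samples. After seeing the data, rescaling without repeat-like and haemoglobin genes, voom on recovered reads, leaving out the 4 libraries above 1% Gm10800, and leaving out each normal sample for immunoglobulin and Myc values were added. Reads were not analysed here.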

Results

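RNA was sequenced from 27 samples of B220-purified mouse B cells, B220 being a surface antigen carried by B cells. 8 samples were non-malignant splenic B cells, 1 untreated and 1 treated with lipopolysaccharide (LPS, a bacterial cell wall component that drives B cells to divide) for 2 days from each of the wt, hv, cr and co genotypes in the labels. The other 19 were B-cell lymphomas of c-myc Igh transgenic mice, 7 labelled hv, 7 cr and 4 co, and 1 whose labels disagreed between hv and co. The lymphomas came from lung (12 samples) or lymph nodes (7 samples). The labels do not say whether the samples came from separate mice, so the p-values measure the spread between these samples. The deposited values were TPM, a relative abundance per transcript that sums to the same total in every sample, which were summed per gene. The depth implied by the TPM steps was about 11530400 to 32029600 read pairs per sample, with a median of 21463300.

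A few transcripts took large shares of the libraries. The predicted gene Gm20594 held 10.9 to 34.3% of TPM across the samples. Gm10800, a repeat-like predicted gene, held 18.6% in the cr LPS sample, 3.65% in the wt resting sample, 3.08% in the mesenteric node lymphoma cr T6 and 2.70% in the hv LPS sample, and under 1% in each of the others. Haemoglobin genes held 1.15 to 10.99% in the resting samples and at most 0.220% elsewhere.

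Myc (chromosome 15, 61985341 to 61990374 of GRCm38), the gene named in the transgene, was measured at 126 ± 41.1 TPM (SD, n = 4) in resting B cells, 115 ± 43.5 TPM (n = 4) after LPS and 190.3 ± 84.1 TPM (n = 19) in the lymphomas. The lymphomas ranged from 78.8 to 362 TPM. On the log2(TPM + 1) scale the lymphomas differed from resting cells by 0.51 (exact permutation p = 0.149, adjusted p = 0.445 over 6 comparisons, two-sided) and from LPS-treated cells by 0.68 (exact permutation p = 0.068, adjusted p = 0.407). The latter difference was 0.37 without the wt LPS sample and 0.86 without the cr LPS sample (exact permutation p = 0.351 and 0.045, unadjusted). LPS-treated and resting cells differed by -0.18 (exact permutation p = 0.686, adjusted p = 0.686), a value that was 0.14 without the wt LPS sample and 0.023 without the wt resting sample. Both groups joined wt with samples labelled hv, cr and co, and single samples went opposite ways. In wt, Myc was at 184.6 TPM in the resting and 55.0 in the LPS sample. It was higher after LPS in cr (121.3 and 155.3), co (109.9 and 114.9) and hv (89.0 and 136.4). The mean difference thus does not show that Myc was unchanged in each genotype. Whether the inserted copy is counted with the reference transcript is not given in the sources used here.

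**Figure D1:**
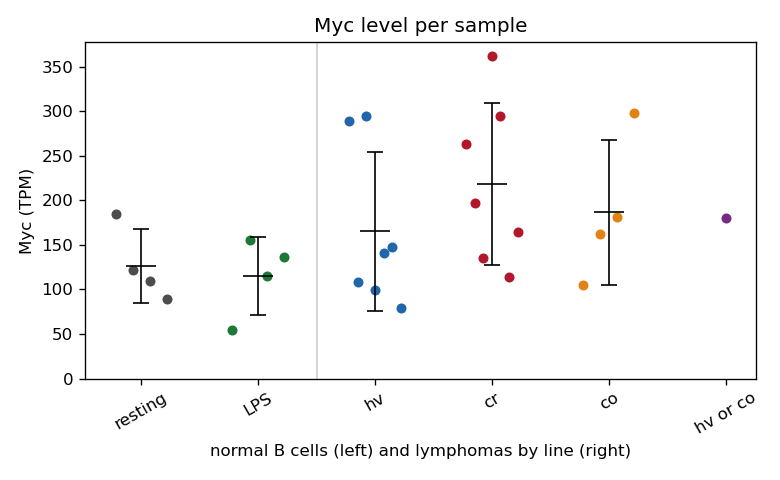
Myc in TPM (vertical axis) in each sample, by group (horizontal axis); points are samples, and bars give the mean and SD of groups with more than 1 sample. The 4 resting samples lay between 89.01 and 185 TPM, within the range of the lymphomas.

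The first comparison asked how non-malignant B cells changed over the LPS treatment. The labels give no time for the untreated cells, so an effect of LPS cannot be told apart from one of the 2 days. Only 1 sample per group was wt, and the others carried the labels hv, cr and co of the transgenic lines. Genes of growth, division and metabolism rose and genes of follicular and naive B cells fell, though no list call of this comparison held with an estimated correlation. The transcription factor gene Zbtb32 rose, at 142 ± 53.9 against 3.11 ± 1.41 TPM (log2 fold change 5.13 ± 0.30, adjusted p = 5.4e-07; errors of fold changes are SE and those of TPM are SD). Bcat1, encoding a branched-chain amino acid transaminase, was at 69.7 ± 12.2 against 2.59 ± 1.27 TPM (log2 fold change 4.34 ± 0.24, adjusted p = 1.7e-07). Fos, an immediate early transcription factor gene, fell, at 4.02 ± 1.76 against 511 ± 217 TPM (log2 fold change -6.66 ± 0.33, adjusted p = 4.3e-07). In all, 6981 of 11999 genes passed an adjusted p of 0.05 by limma, 3026 higher and 3955 lower, with 4 samples per group. The median log2 fold change of the tested genes was -0.16, and changes are best read relative to it.

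MYC targets rose in 29 of 30 (29 adjusted over the list alone) cases (camera adjusted p = 1.4e-13, and adjusted p = 0.369 with an estimated correlation), among them Ldha, encoding lactate dehydrogenase (3.34 ± 0.19), Srm (2.89 ± 0.26) and Hspd1 (2.82 ± 0.22). Ribosome biogenesis genes rose in 30 of 30 (30 adjusted over the list alone) cases (camera adjusted p = 2.3e-12, and adjusted p = 0.369 with an estimated correlation), with Nop16 at 2.23 ± 0.21 and Nolc1 at 2.17 ± 0.19. S phase (DNA replication) genes rose in 29 of 30 (29 adjusted over the list alone) cases (camera adjusted p = 2.3e-13, and adjusted p = 0.369 with an estimated correlation), with Mcm10 at 2.98 ± 0.28 and Uhrf1 at 2.79 ± 0.32. G2/M genes rose in 26 of 30 (26 adjusted over the list alone) cases (camera adjusted p = 1.5e-09, and adjusted p = 0.443 with an estimated correlation), with Cdc20 at 3.02 ± 0.33 and Plk1 at 2.79 ± 0.36. Mki67, a proliferation marker of the G2/M list, did not pass (log2 fold change 0.69 ± 0.54, adjusted p = 0.310). Replication-dependent histone genes rose in 14 of 20 (16 adjusted over the list alone) cases (adjusted p = 0.473 with an estimated correlation). Of the nucleotide and one-carbon genes, 18 of 20 (18 adjusted over the list alone) rose and 1 fell (adjusted p = 0.369 with an estimated correlation), with Psat1 at 3.29 ± 0.19 and Shmt1 at 3.10 ± 0.33.

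Glycolysis genes rose in 14 of 18 (16 adjusted over the list alone) cases (camera adjusted p = 1.5e-09, and adjusted p = 0.369 with an estimated correlation), including the lactate transporter gene Slc16a3 (4.04 ± 0.27) and Tpi1 (3.65 ± 0.22). Cholesterol synthesis genes rose in 17 of 18 (17 adjusted over the list alone) cases (camera adjusted p = 8.0e-09, and adjusted p = 0.369 with an estimated correlation), with Fdps at 3.12 ± 0.34 and Idi1 at 2.74 ± 0.21. Oxidative phosphorylation genes rose in 24 of 25 (24 adjusted over the list alone) cases (adjusted p = 0.369 with an estimated correlation), with Cyc1 at 1.61 ± 0.19. Of the unfolded protein response list 18 of 25 (18 adjusted over the list alone) rose and 2 fell (adjusted p = 0.369 with an estimated correlation), with the amino acid synthesis gene Asns at 3.47 ± 0.55 and Ddit3 at -2.52 ± 0.34. The other genes with the largest rises were Tmed6 (4.22 ± 0.40), Shisa8 (4.18 ± 0.29), the amino acid transporter gene Slc7a3 (4.08 ± 0.24), Ak4 (4.01 ± 0.20), the fatty acid desaturase gene Fads2 (3.76 ± 0.28) and Wnt10a (3.65 ± 0.29).

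Follicular and naive B-cell genes fell in 19 of 20 (19 adjusted over the list alone) cases (camera adjusted p = 6.4e-08, and adjusted p = 0.369 with an estimated correlation), with the quiescence factor gene Klf2 at -4.34 ± 0.29 and Ighd at -3.51 ± 0.57. MHC class II genes fell in 11 of 12 (12 adjusted over the list alone) cases (camera adjusted p = 2.1e-06, and adjusted p = 0.369 with an estimated correlation), with H2-Oa at -3.46 ± 0.31 and H2-Aa at -2.36 ± 0.25. Immediate early genes fell in 19 of 20 (19 adjusted over the list alone) cases (camera adjusted p = 1.8e-08, and adjusted p = 0.369 with an estimated correlation), with Fosb at -5.49 ± 0.26 and Dusp1 at -4.65 ± 0.20. Interferon response genes fell in 18 of 25 (19 adjusted over the list alone) cases (camera adjusted p = 1.7e-04, and adjusted p = 0.473 with an estimated correlation), with Rsad2 at -5.27 ± 0.75. B-cell receptor signalling genes fell in 14 of 25 (14 adjusted over the list alone) cases and general B-cell markers in 9 of 10 (9 adjusted over the list alone) cases (adjusted p = 0.645 and 0.473 with an estimated correlation), with Cr2 at -3.24 ± 0.61 and Ebf1 at -2.09 ± 0.36. Plasma cell genes went both ways, 10 higher and 2 lower of 18 (adjusted p = 0.369 with an estimated correlation), with Prdm1, a plasma cell regulator, at 2.27 ± 0.29. Of the 51 fixed single genes, 43 were measured, of which 14 rose and 14 fell. The cyclin gene Ccnd2 was at 1.71 ± 0.30, and the MYC antagonist genes Mxd1 and Mxd4 at -2.87 ± 0.45 and -2.21 ± 0.20. The lists of marginal zone and B1 cells, germinal centre, early B-cell development, NF-kappaB, p53 targets, the BCL2 family, ribosomal proteins and T cells were not called by camera, with 4 and 7, 7 and 7, 2 and 5, 6 and 7, 9 and 7, 5 and 5, 3 and 0 and 0 and 2 members higher and lower in that order.

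Markers of other cells fell over the same contrast. Erythroid markers fell in 9 of 9 (9 adjusted over the list alone) cases, with Slc4a1 at -6.58 ± 0.91, Hbb-bt at -6.19 ± 1.01, Alas2 at -6.07 ± 0.91 and, outside the list, the blood group gene Kel at -5.79 ± 0.64. Macrophage markers fell in 11 of 13 (11 adjusted over the list alone) cases, with C1qa at -6.08 ± 0.66, C1qc at -5.90 ± 0.60 and C1qb at -5.70 ± 0.66. Platelet markers fell in 4 of 5 (4 adjusted over the list alone) and NK markers in 5 of 5 (5 adjusted over the list alone) cases. Markers of the joint pancreas and adipose list fell in 5 of 5 (5 adjusted over the list alone) cases. These lists had adjusted p = 0.369, 0.389, 0.369, 0.451 and 0.369 in that order with an estimated correlation. Dendritic cell markers were not called as a list (camera adjusted p = 0.202), with 5 of 8 lower, and 1 higher when adjusted over the list alone. Apol11b fell as well (-6.07 ± 0.58). With median-of-ratios scaling the calls were 7747, 3910 higher and 3837 lower, and without the libraries above 1% Gm10800 they were 5531, 3071 higher and 2460 lower, so the share of higher calls went from 43.3% to 55.5%. It was 37.2% with TPM rescaled without the repeat-like and haemoglobin genes.

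The next comparison set the 19 lymphomas against the 4 resting samples, of which 1 was wt and the others carried the line labels. Malignancy cannot be told apart from site, since all non-malignant cells came from spleen. Growth and division genes were higher in the lymphomas, and genes of follicular and naive B cells were lower, though no list call of this comparison held with an estimated correlation. Cr2, encoding the complement receptor CD21, fell, at 5.90 ± 8.87 against 525 ± 252 TPM (log2 fold change -6.89 ± 0.67, adjusted p = 3.0e-08), and Fcer2a, encoding CD23, fell, at 9.40 ± 32.96 against 120.3 ± 61.3 TPM (log2 fold change -5.45 ± 0.85, adjusted p = 3.3e-05). Cd59b, encoding a complement regulator, rose, at 267 ± 129.6 against 25.2 ± 7.48 TPM (log2 fold change 3.28 ± 0.31, adjusted p = 1.5e-08), and Bcat1 rose, at 42.8 ± 32.2 against 2.59 ± 1.27 TPM (log2 fold change 3.22 ± 0.63, adjusted p = 3.7e-04). Of 13239 genes, 4229 passed by limma, 1921 higher and 2308 lower.

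MYC targets rose in 27 of 30 (28 adjusted over the list alone) cases (camera adjusted p = 2.7e-15, and adjusted p = 0.144 with an estimated correlation), with Ldha at 1.86 ± 0.25 and Srm at 1.65 ± 0.25. Ribosome biogenesis genes rose in 25 of 30 (29 adjusted over the list alone) cases (camera adjusted p = 1.6e-11, and adjusted p = 0.154 with an estimated correlation), with Nhp2 at 1.34 ± 0.21. S phase genes rose in 25 of 30 (27 adjusted over the list alone) cases (camera adjusted p = 6.3e-13, and adjusted p = 0.255 with an estimated correlation), with Uhrf1 at 2.00 ± 0.32. G2/M genes rose in 19 of 30 (23 adjusted over the list alone) cases (camera adjusted p = 2.8e-09, and adjusted p = 0.319 with an estimated correlation), with Bub1b at 1.96 ± 0.39. Mki67 did not pass (log2 fold change 0.43 ± 0.41, adjusted p = 0.445), against the same resting samples of uneven G2/M level. Oxidative phosphorylation genes rose in 22 of 25 (22 adjusted over the list alone) cases, with Cox5b at 1.49 ± 0.20 (adjusted p = 0.154 with an estimated correlation). Nucleotide and one-carbon genes rose in 16 of 20 (17 adjusted over the list alone) cases with 2 lower (adjusted p = 0.144 with an estimated correlation). Glycolysis genes rose in 8 of 18 (9 adjusted over the list alone) cases with 1 lower, with Tpi1 at 2.28 ± 0.24 (adjusted p = 0.144 with an estimated correlation). Histone genes rose in 16 of 20 (16 adjusted over the list alone) cases (adjusted p = 0.371 with an estimated correlation). The other genes with the largest rises were Bag2 (2.86 ± 0.58), Sapcd2 (2.57 ± 0.44), the transcription factor gene Bhlhe41 (2.54 ± 0.35), Hepacam2 (2.52 ± 0.32), Akap1 (2.31 ± 0.28), Cpn1 (2.27 ± 0.81) and Cdca7 (2.21 ± 0.38).

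Interferon response genes fell in 22 of 25 (22 adjusted over the list alone) cases (camera adjusted p = 3.5e-15, and adjusted p = 0.144 with an estimated correlation), with Rsad2 at -6.48 ± 0.45 and Isg15 at -4.74 ± 0.50. Follicular and naive B-cell genes fell in 17 of 20 (18 adjusted over the list alone) cases (camera adjusted p = 6.6e-07, and adjusted p = 0.154 with an estimated correlation), with Satb1 at -5.67 ± 0.69. NF-kappaB genes fell in 15 of 24 (17 adjusted over the list alone) cases (camera adjusted p = 1.2e-05, and adjusted p = 0.319 with an estimated correlation), with Cd83 at -3.65 ± 1.20 and the survival gene Bcl2l1 at -3.27 ± 0.42. MHC class II genes fell in 10 of 12 (10 adjusted over the list alone) cases (camera adjusted p = 8.0e-05, and adjusted p = 0.302 with an estimated correlation), with H2-Aa at -2.06 ± 0.41. Immediate early genes fell in 13 of 20 (15 adjusted over the list alone) cases (camera adjusted p = 8.7e-06, and adjusted p = 0.255 with an estimated correlation), with Klf6 at -3.51 ± 0.54. Of 46 fixed single genes measured, 2 rose, Ncl (0.75 ± 0.29) and Nme1 (1.30 ± 0.27), and 12 fell, among them Bcl6 (-2.30 ± 0.35), Jchain (-2.73 ± 1.02), Ighd (-2.88 ± 0.68) and Igha (-3.65 ± 1.09). Trp53 (log2 fold change -1.28 ± 1.18, adjusted p = 0.422) and Cdkn2a (log2 fold change 2.94 ± 1.48, adjusted p = 0.130) did not pass.

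Erythroid markers fell in 9 of 9 (9 adjusted over the list alone) cases (adjusted p = 0.063 with an estimated correlation), with Hbb-bs at -9.51 ± 0.82, Hba-a2 at -9.35 ± 0.84, Hba-a1 at -9.34 ± 0.80, Hbb-bt at -8.61 ± 0.77, Alas2 at -7.70 ± 0.48, Slc4a1 at -7.67 ± 0.47 and Car2 at -7.24 ± 0.49. Tmcc2 fell beside them (-6.60 ± 0.47). Macrophage markers fell in 9 of 13 (9 adjusted over the list alone) and platelet markers in 5 of 5 (5 adjusted over the list alone) cases. NK markers fell in 6 of 8 (6 adjusted over the list alone) and dendritic cell markers in 6 of 9 (6 adjusted over the list alone) cases. Neutrophil markers fell in 6 of 7 (6 adjusted over the list alone) and pancreas or adipose markers in 5 of 5 (5 adjusted over the list alone) cases. Fibroblast markers rose in 2 of 8 (2 adjusted over the list alone) cases. The macrophage, platelet, NK, dendritic cell, neutrophil, pancreas with adipose, and fibroblast lists had adjusted p = 0.255, 0.063, 0.255, 0.255, 0.391, 0.364 and 0.486 with an estimated correlation. Of the alveolar macrophage and lung epithelium markers 2 and 1 fell. B-cell receptor signalling genes fell in 7 of 25 (7 adjusted over the list alone), general B-cell markers in 3 of 10 (3 adjusted over the list alone) cases, and ribosomal protein genes rose in 5 of 25 (5 adjusted over the list alone) cases (adjusted p = 0.486, 0.402 and 0.486 with an estimated correlation). The count was 6571 with a variance per group, 2746 without the libraries above 1% Gm10800 and 2749 without the wt resting sample. With TPM rescaled after leaving out the repeat-like and haemoglobin genes, the split was 1508 higher and 3234 lower, so 31.8% of calls were higher in place of 45.4%. The share went the other way with median-of-ratios scaling (52.5%) and among genes with a mean TPM of 5 or more (57.8%), so the balance of higher and lower calls depends on the scaling and the filter, while no gene called in the main result changed sign in these 3 settings.

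The change over the LPS treatment, in which LPS and time cannot be told apart, and the lymphoma change share the 4 resting samples. Across 11947 genes, which are not independent replicates, their log2 fold changes had r = 0.734 and a covariance of 0.897. Unchanged groups simulated against the same resting samples gave r = 0.579 and a covariance of 0.0469. With the resting samples split 2 and 2 between the comparisons, r was 0.632 to 0.715 and the covariance 0.822 to 0.883. Erythroid, macrophage, platelet and NK markers, and those of the joint pancreas and adipose list, fell in both comparisons. Neither the splits nor the simulation take out RNA of other cells that the resting samples share. Its part in r, in the covariance and in the shared calls was not tested. 1642 genes were called higher in both comparisons, 1717 lower in both and 19 in opposite directions, counts for which no value of unchanged groups was simulated.

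Set against LPS-treated B cells, the lymphomas had lower levels of glycolysis and cholesterol synthesis genes, and higher levels of some immediate early genes. Here too, effects of LPS and of the time of treatment cannot be told apart. Rras2, encoding a small GTPase, was at 4.14 ± 6.60 against 45.2 ± 13.98 TPM (log2 fold change -4.11 ± 0.78, adjusted p = 8.3e-04), and Slc7a3 at 0.600 ± 1.001 against 22.2 ± 6.67 TPM (log2 fold change -3.94 ± 0.30, adjusted p = 2.7e-09). Fos was at 145 ± 152 against 4.02 ± 1.76 TPM (log2 fold change 4.20 ± 0.77, adjusted p = 6.0e-04), and Tsc22d3, encoding the glucocorticoid-induced leucine zipper, at 155 ± 76.2 against 9.90 ± 3.04 TPM (log2 fold change 3.71 ± 0.36, adjusted p = 9.5e-08). Of 12880 genes, 1782 passed by limma, 679 higher and 1103 lower.

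Cholesterol synthesis genes fell in 16 of 18 (17 adjusted over the list alone) cases (camera adjusted p = 4.7e-22, and adjusted p = 0.014 with an estimated correlation), with Hmgcs1 at -2.49 ± 0.32 and Idi1 at -2.48 ± 0.29. Glycolysis genes fell in 13 of 18 (16 adjusted over the list alone) cases (camera adjusted p = 5.2e-13, and adjusted p = 0.014 with an estimated correlation), with Slc16a3 at -3.36 ± 0.66 and Aldoa at -2.52 ± 0.40. These were the only list calls of this comparison to hold with an estimated correlation. MYC targets fell in 14 of 30 (19 adjusted over the list alone) cases, with Mthfd2 at -1.53 ± 0.25 (adjusted p = 0.330 with an estimated correlation). Ribosome biogenesis genes fell in 15 of 30 (17 adjusted over the list alone) cases (adjusted p = 0.443 with an estimated correlation). G2/M genes fell in 11 of 30 (15 adjusted over the list alone) cases, with Aurka at -1.56 ± 0.25 (adjusted p = 0.443 with an estimated correlation). Nucleotide and one-carbon genes fell in 14 of 20 (15 adjusted over the list alone) cases (adjusted p = 0.273 with an estimated correlation). NF-kappaB genes fell in 10 of 25 (11 adjusted over the list alone) cases, with Traf1 at -3.54 ± 0.87 and Ccl22 at -3.41 ± 0.20 (adjusted p = 0.443 with an estimated correlation). Interferon response genes fell in 6 of 25 (10 adjusted over the list alone) cases, with Oasl1 at -3.75 ± 0.32 and Isg15 at -3.10 ± 0.47 (adjusted p = 0.443 with an estimated correlation). Immediate early genes rose in 6 of 20 (7 adjusted over the list alone) cases with 1 lower (adjusted p = 0.443 with an estimated correlation), with Fosb at 3.40 ± 0.69.

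The other genes with the largest falls were Fads2 (-3.61 ± 0.33), Bnip3 (-3.46 ± 0.60), Batf (-3.15 ± 0.49), Ak4 (-3.10 ± 0.55) and Plpp1 (-3.09 ± 0.47). Those with the largest rises were Hepacam2 (2.95 ± 0.32), Crip1 (2.91 ± 0.51), Sorcs2 (2.88 ± 0.44), Dusp5 (2.85 ± 0.62), Sspn (2.68 ± 0.32), Diras2 (2.59 ± 0.34), Scml4 (2.57 ± 0.38) and Acp5 (2.55 ± 0.43). Of 46 fixed single genes measured, 3 rose, Mxd1 (0.88 ± 0.24), Mxd4 (2.32 ± 0.44) and Cd79a (0.75 ± 0.25), and 11 fell, among them Prdm1 (-2.44 ± 0.46), Ccnd2 (-3.17 ± 1.03) and Bcl2l1 (-2.24 ± 0.35). Macrophage markers were higher in 4 of 12 (6 adjusted over the list alone) cases, with C1qa at 2.13 ± 0.60, and erythroid markers lower in 6 of 7 (7 adjusted over the list alone) cases (adjusted p = 0.443 and 0.273 with an estimated correlation). With a variance per group 4143 genes passed, 1931 higher and 2212 lower. The count was 1103 without the wt, 835 without the co and 821 without the hv LPS sample. Without the libraries above 1% Gm10800 it was 433, 93 higher and 340 lower, a share of 21.5% higher in place of 38.1%.

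**Figure D2:**
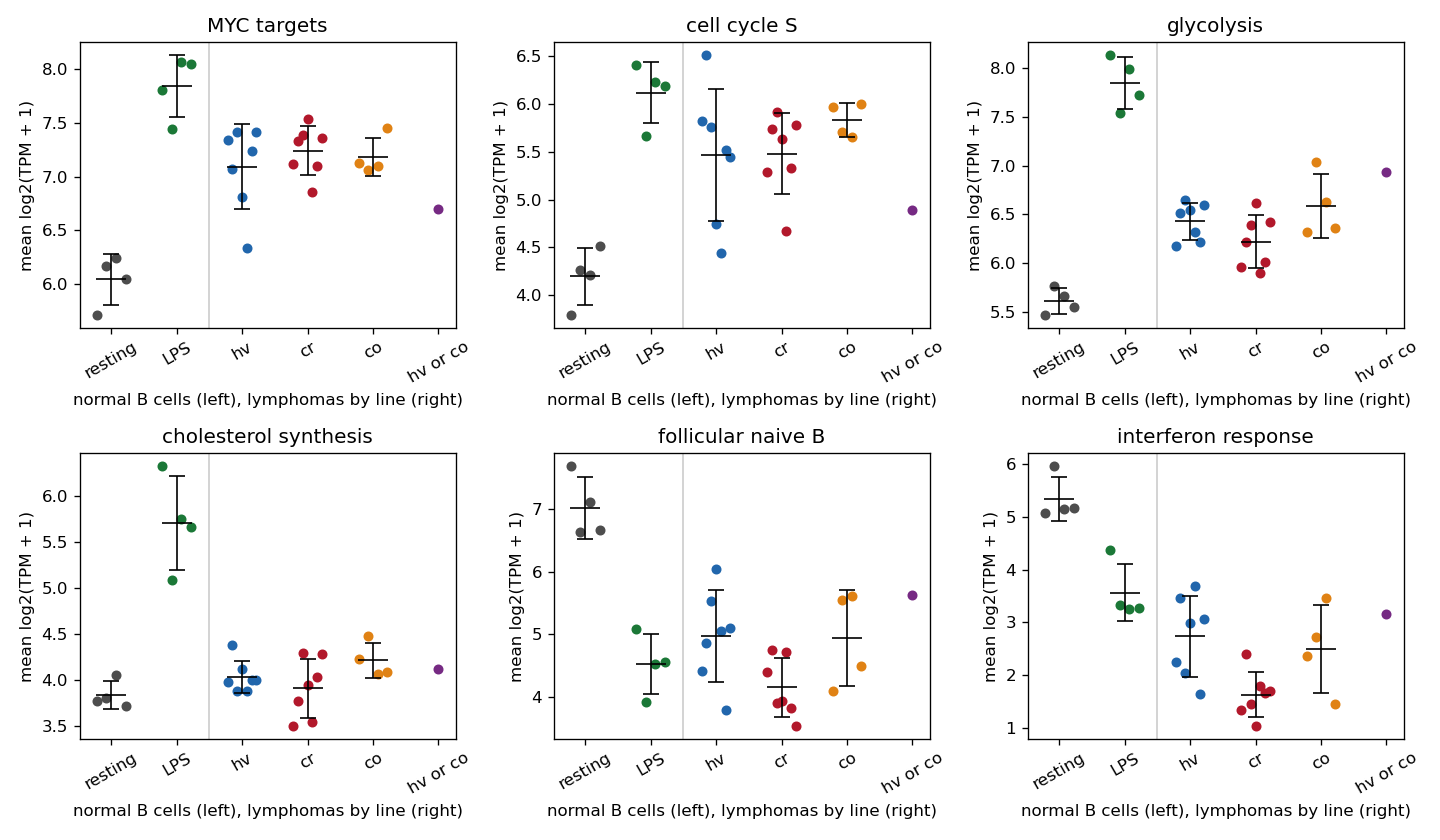
Mean log2(TPM + 1) over the members of 6 fixed gene lists (vertical axes) in each sample, by group (horizontal axes); points are samples, and bars give the mean and SD of groups with more than 1 sample. The 4 LPS-treated samples lay above each lymphoma for glycolysis and cholesterol synthesis, and the 4 resting samples above each for follicular and interferon response genes.

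Immunoglobulin constant regions were compared to describe the isotype of the lymphomas. Ighm took 73.8 ± 3.77% (SD, n = 4) of heavy-chain constant TPM in resting cells, 95.9 ± 0.638% after LPS and 91.5 ± 6.21% in the lymphomas (exact permutation p = 1.1e-04, adjusted p = 0.0030 over 54 tests against resting cells, the smallest p these permutations can give). Ighd took 19.9 ± 2.64% in resting cells and 3.99 ± 3.65% in the lymphomas (exact permutation p = 1.1e-04, adjusted p = 0.0030). Igha took 4.24 ± 3.39% and 0.742 ± 1.24% (exact permutation p = 0.0040, adjusted p = 0.071). Each lymphoma was mainly Ighm, from 78.5 to 98.4%. The lambda share of light chains, from Iglc2 against Igkc, was 16.6 ± 2.43% and 13.7 ± 9.07% (exact permutation p = 0.544, adjusted p = 0.848). LPS-treated against resting cells could not pass after adjustment, since 4 against 4 gives p = 0.029 at best by an exact test. No pair of lines passed for any constant region.

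The use of variable genes was compared because a clone is taken to use mainly 1 rearranged heavy-chain variable gene. The top Ighv gene took 5.68 ± 0.676% of Ighv TPM in resting cells and 86.4 ± 20.53% in the lymphomas (exact permutation p = 1.1e-04, adjusted p = 6.8e-04 over 12 tests), with a lymphoma median of 94.7%. The top Igkv gene took 6.52 ± 0.927% and 74.5 ± 23.8% (exact permutation p = 1.1e-04, adjusted p = 6.8e-04). The mean shares were also above those after LPS, 13.7 ± 12.2% for Ighv (exact permutation p = 2.3e-04, adjusted p = 9.0e-04) and 15.7 ± 16.8% for Igkv (exact permutation p = 6.8e-04, adjusted p = 0.0020). Without the cr LPS sample the means after LPS were 7.82 ± 4.08% and 7.27 ± 0.249% (n = 3). The lowest Ighv shares among lymphomas were 26.7% in lung co T30 and 48.4% in lung T39, the sample with disagreeing labels, and the lowest Igkv shares 20.2% in lung hv T7 and 20.2% in node hv T8. The cr LPS sample, at 31.2% and 40.8%, lay above co T30 for Ighv and above hv T7 and hv T8 for Igkv. Reads of related variable genes can be split between them by the counting, so these shares are uncertain to that degree. No pair of lines differed past the threshold.

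**Figure D3:**
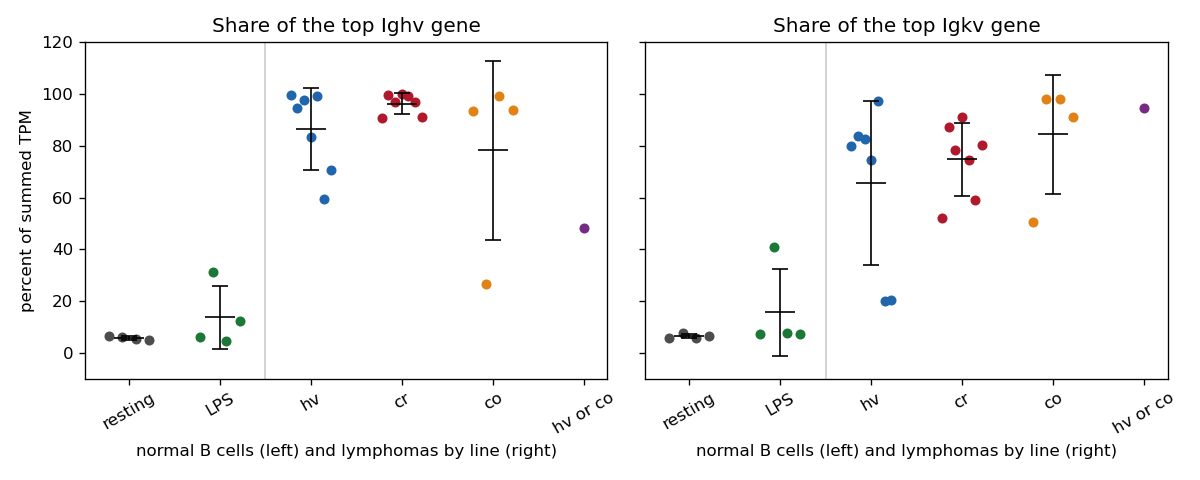
Percent of summed Ighv TPM (left) and Igkv TPM (right) taken by the top gene of each sample (vertical axes), by group (horizontal axes); points are samples, and bars give the mean and SD of groups with more than 1 sample. Resting samples lay between 4.96 and 6.38% for Ighv, below each lymphoma.

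The lines were compared among the 18 lymphomas with agreeing labels, with site as a covariate. Between hv and cr no gene passed by limma, with 1140 of 12480 at an unadjusted p under 0.05 and 0 by voom. The smallest p-values belonged to Ms4a6b (log2 fold change 1.93 ± 0.39, adjusted p = 0.546), Pxk (log2 fold change 0.78 ± 0.18, adjusted p = 0.546) and Shisa5 (log2 fold change 2.74 ± 0.67, adjusted p = 0.546). Between hv and co no gene passed by limma either, with 429 at an unadjusted p under 0.05 and 0 by voom, and the smallest p-values were those of Parp8 (log2 fold change -2.51 ± 0.49, adjusted p = 0.922), Arfgef2 (log2 fold change 0.87 ± 0.18, adjusted p = 0.948) and Calcrl (log2 fold change -1.78 ± 0.39, adjusted p = 0.948). Between cr and co 1 gene passed, Calcrl, encoding a calcitonin receptor-like receptor, which was lower in cr at 0.399 ± 0.304 against 9.48 ± 7.20 TPM (log2 fold change -2.66 ± 0.41, adjusted p = 0.050), with 0 by voom. That call was lost on leaving out any 1 cr sample, co T30 or co T34, and the count was 10 without co T9 and 4 without co T2. It was also lost in lung lymphomas only and in joined names only, where other genes were called. Myc differed by -0.45 ± 0.35 between hv and cr, -0.24 ± 0.40 between hv and co and 0.21 ± 0.41 between cr and co, none past the threshold. Camera with its preset correlation called 15, 9 and 8 lists in these 3 comparisons, none of which held with an estimated correlation (smallest adjusted p = 0.463, 0.919 and 0.890).

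Lymph node lymphomas were compared with lung lymphomas, with line as a covariate. Srp19, encoding a subunit of the signal recognition particle, was lower in lymph nodes at 20.95 ± 6.03 against 49.7 ± 13.8 TPM (log2 fold change -1.34 ± 0.21, adjusted p = 0.029, n = 7 and 11, limma). The other of the 2 calls among 12480 genes was a ribosomal protein pseudogene that was higher in lymph nodes. The counts without single node samples ran from 0 to 5, with 0 without hv T15, hv T8, cr T35 or co T2, 1 without cr T1 or cr T20 and 5 without cr T6. Srp19 kept its call only without cr T6, and lost it without each of the other 6 node samples. Myc was at 0.015 ± 0.32. Site also followed the way sample names were written: samples with joined names were all from lung, and of the lung lymphomas with agreeing labels only 2 had separated names, so the count of 0 within that style (2 lung and 7 node samples) says little.

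Across the 19 lymphomas, Myc was set against the mean of 5 gene lists. Pearson's r was 0.271 with MYC targets (rho = 0.353, permutation p = 0.263 and 0.138, adjusted p = 0.439 and 0.345) and 0.394 with ribosome biogenesis (rho = 0.398, permutation p = 0.093 and 0.092, adjusted p = 0.422 and 0.345). It was 0.0128 with S phase genes, 0.0327 with G2/M genes and -0.330 with p53 targets (rho = 0.0491, -0.00877 and -0.281, permutation p = 0.959, 0.897 and 0.169 for r). No relation passed adjustment over the 5. Without the 2 lymphomas farthest from the median Myc, r with ribosome biogenesis was 0.437 and with MYC targets 0.320. Within hv and within cr, with 7 samples each, r with ribosome biogenesis was 0.302 and 0.381, and r with MYC targets was 0.278 and -0.0183. With median-of-ratios scaling r was 0.568 with ribosome biogenesis and 0.487 with MYC targets (permutation p = 0.011 and 0.034, adjusted p = 0.053 and 0.085). In the 12 lung lymphomas r was 0.619, 0.428 and, for p53 targets, -0.0452 (permutation p = 0.033, 0.165 and 0.886), none past adjustment.

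2 fixed tumour suppressor genes varied widely between single lymphomas. Trp53 (chromosome 11, 69580359 to 69591873 of GRCm38), encoding p53, was at 0.275 TPM in lung hv T1, 1.43 in lung hv T14, 0.552 in lung co T30, 0.409 in lung cr T16 and 0.192 in node co T2, and at 41.8 to 84.5 TPM in the other 14. The low values rest on 10.1 to 67.01 read pairs. Cdkn2a (chromosome 4, 89274471 to 89294653), encoding p16 and p19, was at 108, 80.5, 169.9, 120.03 and 109.6 TPM in those 5 lymphomas in the same order, and ranged from 0 to 124 TPM in the others. These are values of single samples, and no test between them was run.

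**Figure D4:**
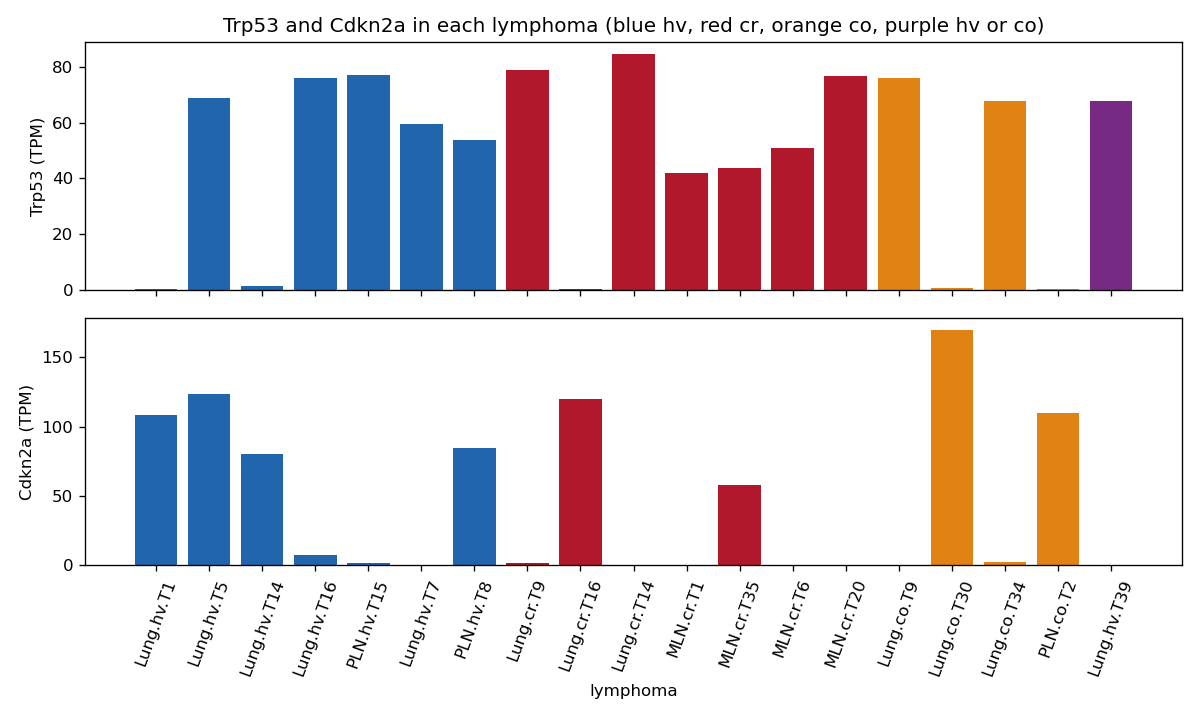
Trp53 (top) and Cdkn2a (bottom) in TPM (vertical axes) in each of the 19 lymphomas (horizontal axis), with bars coloured by line. The 5 lymphomas with Trp53 under 2 TPM had Cdkn2a between 80.5 and 169.9 TPM.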

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

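The test of depth in the pattern below was chosen only after the result was seen, in place of an earlier one that rested on 1 library, while the test of genomic DNA was written before. Single samples were compared with the others of their group by the ratio of the gap to the nearest sample over the range, in 265 groups of 53 measures; 36 values of single samples stood apart, where chance gives about 5% of groups. Shares are percent of heavy-chain constant TPM or of variable gene TPM, and list values are mean log2(TPM + 1) over members.

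Gm10800 took 18.6% of TPM in the cr LPS sample against 2.70% in the next LPS sample, and 3.08% in mesenteric node cr T6 against 0.544%. With the wt resting and hv LPS samples these are the 4 libraries above 1%. Among genes with 1 transcript, these 4 had a larger number with 1 to 20 read pairs (4456 or more). Lower depth was excluded as the cause of this, since 3 libraries were shallower than all 4 and had at most 3036. Genomic DNA may be the source and stays open: the lowest summed TPM of olfactory and vomeronasal receptor genes in the 4 was 31.2 against a median of 21.9 in the others, but another library reached 75.5, although receptor genes above 0 numbered 247 to 691 in the 4 and at most 108 elsewhere. No biological explanation was tested.

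Among the resting samples, the hv sample stood apart with 0.319% Ighg1, 5.31 for the unfolded protein response and 1.99 for early B-cell development. The cr resting sample had 5.96 for interferon response genes, 3.64 for dendritic cell and 3.68 for platelet markers. Among the LPS samples, the cr sample had 40.8% of Igkv TPM in Igkv12-89, 7.18 for oxidative phosphorylation and 10.43 for ribosomal proteins, and the wt sample 4.37 for interferon response.

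Among the hv lymphomas, lung T16 had 0.00820% Ighe. Lung T7 had 3.94% Igha, 3.61 for the joint list of pancreas and adipose markers against 0.16 in the next sample, and 0.0308% Gm10800. Node T15 had 5.13 for ribosome biogenesis. Among the co lymphomas, lung T9 had 0.718% Ighg1, 1.34% Ighg2b, 1.10% Ighg2c, 2.34% Igha and 50.4% of Igkv TPM in its top gene. Lung co T30 had 0.561% Ighe and 26.7% of Ighv TPM in its top gene. Node co T2 had 7.45 for MYC targets, and lung co T34 0.73 for platelet markers and 0.111% haemoglobin.

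Among the cr lymphomas, node T35 had 13.9% Ighd and 34.3% of TPM in Gm20594. Node T20 had 0.263% Ighg1 and 3.81% Igha, and node T6 0.00490% Ighe. Lung T16 had 0.437% Ighg3 and 1.85 for fibroblast markers, lung T9 2.07 for neutrophil markers and node T1 2.26 for early B-cell development.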

How the results depend on the processing

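Rescaling without repeat-like and haemoglobin genes, voom, leaving out the libraries above 1% Gm10800 and leaving out normal samples for immunoglobulin and Myc values were chosen after seeing the data. The cause of each change below was not tested. LPS against resting gave 16381 called transcripts when these were tested singly, and leaving out each sample gave 5874 to 7070. Lymphoma against resting gave 6571 with a variance per group, 8587 for single transcripts, 2746 without the libraries above 1% Gm10800, 2749 with the 3 transgenic lines as normal, and 2749 to 3222 on leaving out each resting sample. Lymphoma against LPS gave 4143, 3157, 433 and 1103 under the same 4 settings, and 821 to 1392 on leaving out each LPS sample. The median log2 fold change shifted by 0.13 and 0.11 with median-of-ratios scaling, and by -0.13 and -0.13 with the rescaling, for LPS and for lymphoma against resting.

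Between hv and cr the count was 1 with no filter on low values, 1 for lung lymphomas only and 1 for joined names only, against 0 in the main result. Between hv and co it was 1 with no filter and 3 for joined names only. Between cr and co it was 0 with a pseudocount of 0.1 or 5, no filter, a mean TPM of 5 or more, rescaling without immunoglobulin and mitochondrial genes, single transcripts, rescaling without repeat-like and haemoglobin genes, voom, without the libraries above 1% Gm10800, name style as covariate, or the disagreeing sample as hv, and 4 for joined names only. In these joined names, and in lung lymphomas only, Calcrl was not among the called genes. Leaving out each cr or co sample gave 0 to 10. Lymph node against lung gave 0 with no filter, hv and cr only, or separated names only (2 lung samples), 1 with a mean TPM of 5 or more, median-of-ratios scaling, no trend, or voom (of these 4 settings Srp19 kept its call only with a mean TPM of 5 or more), 20 for single transcripts, 5 without the libraries above 1% Gm10800, and 0 to 5 on leaving out each node sample. Leaving out each hv, cr or co sample kept hv against cr and hv against co at 0.

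Myc against S phase and G2/M genes gave r of -0.0730 and -4.38e-04 in lung lymphomas only. The correlation of the LPS and lymphoma changes was 0.690, 0.632, 0.682, 0.660 and 0.667 in 5 of the splits of the resting samples. The Myc difference of lymphoma against LPS ranged from 0.37 to 0.86, and of LPS against resting from -0.35 to 0.14, on leaving out each normal sample. Some genes not past the threshold changed sign. Myc did so in LPS against resting (0.34 without wt, 0.023 and 0.14 without the wt resting or LPS sample). Mki67 did so in lymphoma against resting (-0.10 without the libraries above 1% Gm10800 and -0.10 without the wt resting sample, which is also the setting with 3 transgenic lines as normal; the range over single resting samples was -0.10 to 0.87). Myc did so in hv against cr (0.13 for joined names only). In hv against co it was 0.21 for lung only, 0.52 for joined names only and 0.084 without co T2, with -0.48 without co T9 as the other end of the range. In cr against co it was -0.011 without co T9 and 0.61 without co T2. In lymph node against lung it was -0.23 for hv and cr only, -0.20 for separated names, and -0.10, -0.058 and -0.23 without node cr T1, cr T35 or co T2, the highest being 0.24 without hv T8. No called gene named here changed sign. Of 101 camera calls of lists, 2 held with an estimated correlation.

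Whether the replicate numbers pair the samples stays open. The closest sample of the other group carried the same line for cr and co and the same number for T1 and T16. It did not for wt, hv and T14. The deviations of resting and LPS samples of a line correlated at 0.0585 for wt, 0.222 for cr, 0.340 for co and 0.0630 for hv, and a line block gave 7250 genes in place of 6981, of which 6853 were shared. Tumour numbers T1, T14 and T16 correlated at 0.275, -0.297 and 0.0566 between hv and cr, and that block gave 0 genes, with Myc at 0.067. Most tumour numbers occur once, so this block leaves little to estimate the spread from, and its count says nothing about pairing. Depth limits values below about 3 read pairs.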

Other observations

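Among these tests, loss of Trp53 alone, the reach beside Mtap and the depth of the libraries (in place of an earlier test that rested on 1 library) were chosen after the result was seen, as were the scans without predicted genes and without the loci of Trp53 and Mtap. Some lists not described in the report changed between lymphomas and LPS-treated cells. Unfolded protein response genes fell in 12 of 25 (15 adjusted over the list alone) cases and rose in 2 (adjusted p = 0.273 with an estimated correlation). S phase genes fell in 5 of 30 (11 adjusted over the list alone) cases (adjusted p = 0.551 with an estimated correlation). The p53 targets fell in 7 of 23 (7 adjusted over the list alone) cases with 2 higher (adjusted p = 0.443 with an estimated correlation). Oxidative phosphorylation genes fell in 2 of 25 (1 adjusted over the list alone) cases (adjusted p = 0.637 with an estimated correlation). General B-cell markers were higher in 4 of 10 (4 adjusted over the list alone) and fibroblast markers in 1 of 8 (5 adjusted over the list alone) cases (adjusted p = 0.443 and 0.443 with an estimated correlation).

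Trp53 lay under 2 TPM in 5 of the 19 lymphomas. Wrap53, which lies directly ahead of it on the other strand, was at 0.159, 0.147, 0.0723 and 0.0730 TPM in lung hv T14, lung co T30, lung cr T16 and node co T2 against a lymphoma median of 10.9, but at 5.12 in lung hv T1. Fxr2, on the other side, was at 0.781 and 1.57 TPM in co T30 and cr T16 against a median of 37.2. In hv T1, hv T14 and co T2 it was at 46.7, 52.2 and 18.3. A loss of the region may account for part of these values, since the lowest neighbour was at 0.661% of its median. A neighbour was under 25% of its median in 4 of the 5 and in 0 of the other lymphomas, by a rule chosen after these values were seen. In co T30 and cr T16 both neighbours were that low, which argues against loss of Trp53 alone in these samples. In hv T14 and co T2 only Wrap53 was that low. Since Wrap53 lies directly beside Trp53, its level cannot exclude a loss confined to the Trp53 end there. Both neighbours were that low in 2 of the 5, so how far a loss reaches in the others, and whether there is one in hv T1, stays open. The DNA was not analysed here.

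Mtap, beside Cdkn2a and Cdkn2b on chromosome 4, lay under 1 TPM in 6 lymphomas. These were lung cr T14 (0.190), lung hv T7 (0.161), node cr T1 (0.162), node cr T6 (0.176), node cr T20 (0.220) and lung T39 (0.617), against a median of 17.6. In a scan of 8272 genes, 21 adjacent pairs were both under 5% of their lymphoma medians in the same sample, against at most 12 and on average 1.19 in 1000 shuffles of gene order. There were 13 against at most 8 without predicted genes, but 8 of these lay at Trp53 and Mtap, which prompted the scan. Elsewhere 5 pairs were left, against at most 8 and on average 1.08 in the shuffles, of which 28 of 1000 had as many. Pairs elsewhere do not decide on loss of neighbouring genes together at Mtap, which stays open. In the 6 lymphomas Cdkn2a was at 0 to 0.450 and Cdkn2b at 0 to 0.0706 TPM, but in the other 13 they ranged from 0.0584 to 169.9 and 0.0575 to 7.01 TPM, so low values also came with Mtap kept. Klhl9, the next gene on the far side from Cdkn2a with a median TPM of 5 or more, was low with Mtap in 2 of the 6, at 0.0803 TPM in node cr T1 and 0.471 in lung T39 (median 33.99). It was at 73.1% of its median in lung cr T14, 74.4% in lung hv T7, 76.3% in node cr T6 and 92.7% in node cr T20. These values argue against a low stretch of RNA that reaches Klhl9 in those samples. Its reach beyond Klhl9 in node cr T1 and lung T39, and between the genes in the others, stays open. Low depth was excluded as the cause of the low Mtap values, since the depth of each of the 6 libraries gives at least 200.3 read pairs of Mtap at the median TPM, and at most 7 were seen.

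Samples were split anew into groups of the same sizes. Chance can be excluded for LPS against resting (1 of 35 splits called as many genes, the real one, with 1 in the highest other against 6981). It can be excluded for lymphoma against resting (1 of 100 splits, highest other 1082 against 4229) and lymphoma against LPS (1 of 100, highest other 45 against 1782). For lymph node against lung 2 of 100 splits called as many genes, the real split included (highest other 49 against 2). This share lay under the limit set beforehand. The test still cannot exclude chance there, since the count of 2 fell to 0 without hv T15, hv T8, cr T35 or co T2. The highest other split of this comparison is many times the real count, which points to a structure of the samples, not tested further. For hv against cr and hv against co the real count was 0, which every split reaches, so the splits decide nothing (100 of 100 and 100 of 100 splits, highest other 2 and 772). The split with 772 parted lung hv T14, T16 and T5, node hv T15 and T8, and lung co T30 and T34 from the rest, and what these samples share was not tested. Chance cannot be excluded for cr against co (10 of 100 splits, highest other 6 against 1).

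The top variable genes of single samples are values of interest. The cr LPS sample had 31.2% of Ighv TPM in Ighv1-55, and the hv LPS sample 12.4% in Ighv1-9. Lung hv T1 and lung hv T14 shared the top genes Ighv1-64 and Igkv1-135, and node cr T1 also had Ighv1-64, with Igkv19-93. Igkv1-135 was the top Igkv gene in lung hv T16, lung cr T9 and lung cr T16 as well. Further top genes recurred, such as Ighv1-52 in lung co T30 and lung co T34, and Ighv6-3 in node hv T8 and node cr T20. A shared top gene alone thus does not show a link between samples. Cdkn2a was above 50 TPM in lung hv T5 (124, with Trp53 at 68.96), node hv T8 (84.4, with 53.8) and node cr T35 (57.8, with 43.8), besides the 5 lymphomas with low Trp53. Rag1, a gene of variable region recombination, was at 27.8 TPM in lung co T9, 46.7 in lung cr T9 and 58.2 in node cr T35.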
